A study of Homo sapiens with 70 samples.

How the data were processed

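Chromatin immunoprecipitation and sequencing was carried out on MCF7 tumours grown in athymic nude mice, with antibodies against estrogen receptor α (ERα), the glucocorticoid receptor (GR), the progesterone receptor (PR), c-JUN and histone H3 acetylated at K27 (H3K27ac). Snap-frozen tumours were fixed with DSG and then formaldehyde and the lysates were sonicated, per the labels' protocols. The submitters' processing notes name BWA, Picard, GATK and MACS2 and the build hg38, also called GRCh38. Program versions, the removal of reads from mouse cells, and the input library set against each immunoprecipitate were not given in the sources used here. Human and mouse DNA are both present in such tumours, and any treatment difference in the share of mouse cells would change the human read number without being seen in the lists.

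Each of the 66 immunoprecipitated libraries had a list of peaks, and the peak names in the lists show that the authors called peaks per library in paired-end mode. The 4 input libraries were not analysed here. Each peak carries a position, a summit and 4 values made by the authors' peak caller. The deposited fold enrichment is the ratio of the summit's signal to the local background, per the file format. The deposited p and q are on a −log10 scale, and the lowest −log10 q in any list was 2.00, so the authors' threshold was a q of 0.01. The deposited integer score was not used. Fold enrichment and p are the authors' values and were used only to rank, filter or describe peaks within a list, never to compare lists. No list gives a read number, so the depth of each library is unknown and no interval that needs it is given. A library with fewer reads or a weaker immunoprecipitation gives fewer peaks, which the lists alone cannot separate from fewer bound sites. Lists held between 344 and 71992 peaks on chromosomes 1 to 22 and X, the only chromosomes used. Other sequences held at most 4.51% of a library's peaks, with a median of 0.121%. No 2 lists were identical.

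Groups came from the labels, which number the replicates but do not say that each came from a separate animal. The p-values therefore measure only the spread between these samples, which may be technical. Fasted libraries are those of the Fasting and TMX plus fasting groups, and fed libraries are those of the Control and TMX groups. For each target, fasted were compared with fed libraries within tamoxifen strata, libraries with tamoxifen were compared with those without it within fasting strata, and the interaction and 4 single pairs of groups were tested as well. The test of single regions, described below, ignored these strata. Differences printed for a stratified test weight both strata equally, so with unequal groups they can depart from the difference of the printed means. Log2 peak numbers, shares and peaks per gene window were tested with two-sided exact stratified permutation tests, which allow 400 relabellings for 12 libraries (smallest p 0.005) and 1680 for 15 libraries (smallest p 0.000595). Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. They were taken over 15 tests of peak number, 55 tests of list shares per contrast, 24 tests of other targets at called regions, and all regions or genes tested.

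Regions were the merged peaks of all libraries of a target that overlapped by at least 1 bp. Each region was tested with a two-sided Fisher exact test on the number of libraries with a peak there, provided that its total number of libraries let p reach 0.05. This test pooled the strata, so fasting and tamoxifen were not balanced for ERα and H3K27ac, where TMX plus fasting had more libraries. Gene positions came from a RefSeq gene table of GRCh38.p14, the build of the lists. That table has no strand, exons or sequence, so windows were placed differently from the design written beforehand. A gene window was the whole span of a gene plus 50 kb on either side in place of 50 kb around its transcription start, and peaks at promoters were replaced by peaks whose summit lay within 1 kb of either end of a gene span, called gene ends here. Motifs could not be searched without a genome sequence. All 19974 protein-coding genes were used, and a gene was tested where at least 3 libraries had a summit in its window. The gene named for a region is the one whose span is nearest within 100 kb, and whether a region lay in an exon or an intron was not resolved.

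There were 11 gene lists with 271 genes in all, every one of which was matched by symbol. They were GR targets, PR targets, ER targets, AP-1 and growth factor targets, fasting with FOXO and amino acid stress genes, cell cycle genes, luminal identity genes, basal markers, fibroblast with endothelial and pericyte markers, immune and adipocyte markers, and housekeeping genes. Genes were named by a rule with 3 parts. FKBP5, TSC22D3, PER1, ZBTB16, KLF9 and SGK1 were always named for GR and PR, GREB1, TFF1, PGR, XBP1, CCND1 and MYC for ERα and H3K27ac, and JUN, FOSL2, ATF3 and CD44 for c-JUN. Next came list genes that passed the fasting test adjusted over the list alone, at most 8 per list by the size of the difference. The last part took, per target, contrast and direction, the 10 called regions with the smallest p, ties being ranked by mean fold enrichment, with 1 region per gene. The samples, tests, lists, naming rule and most alternatives were set before the data were examined. The tamoxifen test of gene windows and the genes it names, the test of other targets at called regions, the comparison with 10000 random gene lists (matched on mean peaks per window of the target, on H3K27ac peaks per window or on gene span), the runs without libraries of fewer than 1000 peaks, and the alternatives for these were added after the data had been seen.

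Alternatives were a −log10 q of at least 5, a fold enrichment of at least 5, equal numbers of the strongest peaks, the 5000 strongest peaks, windows of 100 bp around summits, every region found in 2 or more libraries, every sequence in the lists, windows of 10 kb and 100 kb, no strata, pairing by replicate number, only the first 3 TMX plus fasting libraries, and each library left out in turn. Overlaps between targets used regions found in at least 2/3 of a group's libraries and were set beside 100 random placements on the same chromosome. The scripts were tested on simulated data. For GR, fasted against fed, 200 regions planted in every fasted and no fed library were not recovered (0%, 5070 regions tested), whereas 2000 were recovered in full (100%, with 49 false calls among 6527 tested), because the exact p is coarse and the correction passes it only when many regions share it. For H3K27ac with and without tamoxifen, 200 planted regions were recovered in full (100%, 2 false calls among 28719 tested). For GR gene windows, 200 planted genes were not recovered over all 14740 genes tested (0%), 4000 were recovered at 56.4% (14725 genes tested), and a planted list of 30 genes was recovered at 90.0% when adjusted over the list alone. Without an effect, 4.61% of p-values were under 0.05. The simulated libraries did not differ in list length apart from what was planted, unlike the real GR lists. Their false calls and this share therefore do not measure the error in these data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with random seed 1.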

Results

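Binding of ERα, GR, PR and c-JUN was mapped in tumours of MCF7, an established human breast cancer cell line that carries the estrogen receptor. H3K27ac, a histone mark of active promoters and enhancers, was mapped alongside. Tumour-bearing nude mice received no treatment (Control) or tamoxifen, which competes with estrogen for its receptor (TMX, 30 mg/kg on 5 days a week for 4 weeks). Others were fasted on water alone for 48 h once a week (Fasting) or given both treatments (TMX plus fasting), over 4 cycles. The layout asks whether fasting changes where these factors sit in tumours with and without endocrine treatment. The series title places glucocorticoid signalling at the centre of that question. Every group had 3 libraries per target, except that ERα and H3K27ac had 6 in the TMX plus fasting group, which gave 66 peak lists. Read numbers are unknown, so the number of peaks in a list is the only sign of its depth. H3K27ac lists were the most even, at 54864 ± 5039 peaks in Control, 59525 ± 5139 in TMX and 60764 ± 1988 in Fasting (SD, n = 3 each). The TMX plus fasting group had 59823 ± 6431 (SD, n = 6). GR lists were the shortest. They held 4085 ± 3282 peaks in Control, 2004 ± 1690 in TMX, 20286 ± 3398 in Fasting and 15025 ± 15963 in TMX plus fasting (SD, n = 3 each). The shortest GR list, Control replicate 3, had 344 peaks.

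**Figure D1:**
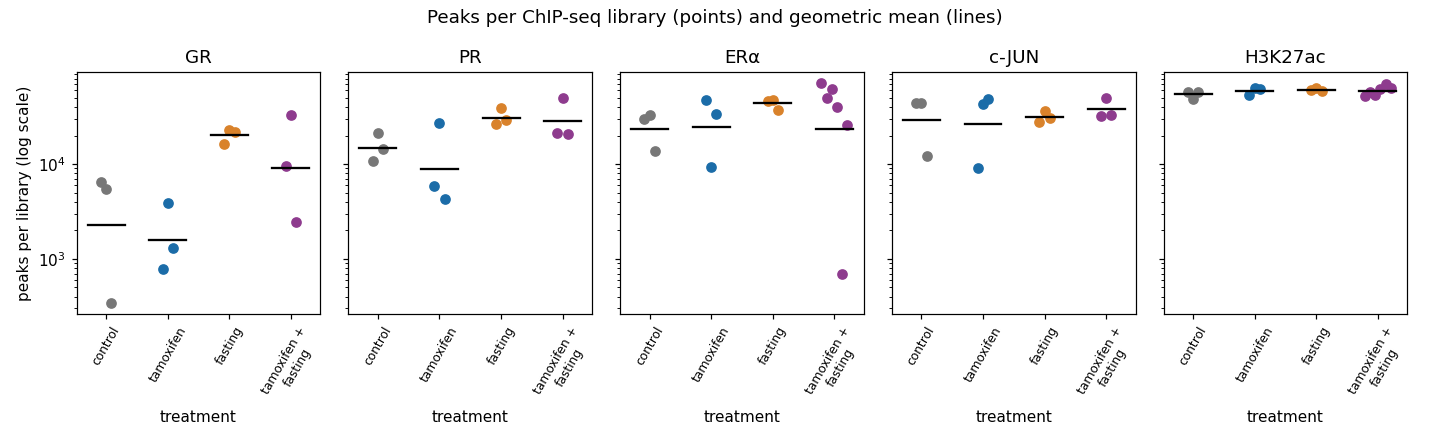
Number of peaks in each library (log axis) by treatment group, with a panel for each of the 5 targets, where points are libraries and lines are geometric means. All 3 Fasting libraries of GR lie above all 6 fed libraries, whereas the H3K27ac libraries of all groups lie close together.

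Peaks of GR, the receptor for cortisol and corticosterone, were called at far more places in tumours of fasted mice. Fed lists held 344 to 6483 peaks and fasted lists 2438 to 32980. Fewer GR sites in fed tumours therefore cannot be told apart from fewer reads or weaker immunoprecipitation. In the counts below, bound means that a peak was called. Of 4918 regions tested, 1895 were bound in more fasted than fed libraries and 3 in fewer (Fisher exact test, Benjamini-Hochberg adjusted p = 0.0393). In 229 of them a GR peak was found in 6 of 6 fasted and 0 of 6 fed libraries. The gained regions had a median width of 1304 bp. Inside a gene span lay 53.2% of them and at a gene end 12.3%, and 1551 genes were the nearest to at least 1 region. All regions named next were bound in 6 of 6 fasted and 0 of 6 fed libraries (exact p = 0.00216). The one with the highest fold enrichment (authors' value, mean 29.5) lay at chromosome 8:54558380-54559611, 184 bp from RP1. Regions inside gene spans followed at ATAD2, a chromatin-binding ATPase (8:123405105-123406350, mean fold enrichment 27.5), and CAMK2D, a calcium-dependent kinase (4:113615851-113617200, mean 26.4). DOCK1, an activator of Rac (10:127357843-127359449, mean 20.9), and C5, a complement component (9:120985451-120986472, mean 18.2), also held one. A region lay 22390 bp from HEATR3 (16:50129008-50130268) and another 6802 bp from HNRNPA0 (5:137760466-137761706). MAX, the partner of MYC, was 15840 bp from its region (14:65117847-65119428). RGS1 was 79257 bp away (1:192495948-192497050) and LOC124900752 was 93907 bp away (4:108264126-108265705). Of the 3 regions with fewer fasted libraries, that at 1:144103351-144104885 was bound in 0 of 6 fasted and 6 of 6 fed libraries, 48321 bp from LOC105371206. The others were bound in 0 fasted and 5 fed libraries. They lay at 15:20340400-20342156, 9302 bp from LOC124903442, and at 15:21110372-21110754, 244335 bp from POTEB2, the last named after its values were seen. The geometric mean number of GR peaks was 13587 in fasted and 1909 in fed libraries, a 7.12-fold difference (log2 2.83, exact stratified permutation p = 0.01, n = 6 and 6). The permutation test did not pass the correction over 15 tests (adjusted p = 0.150), and without Control replicate 3 the difference was 4.43-fold (exact p = 0.015). Leaving out any of Control replicates 1 to 3 or TMX replicates 1 to 3 gave 0 regions (smallest adjusted p 0.0575 to 0.0769, with 1897 to 2466 higher at an unadjusted p under 0.05). Each of these runs tested 9575 to 9696 regions in place of 4918, which made the correction heavier. The loss of calls therefore does not show what a single fed library holds. Without TMX plus fasting replicate 1 or 3 there were 5098 or 6481 higher, and without both lists of fewer than 1000 peaks, Control replicate 3 and TMX replicate 1, there were 0 (1900 higher unadjusted).

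Around genes, mean GR peak numbers were higher in fasted tumours in nearly every window of every list, such as 33 of 33 GR targets, 37 of 37 ER targets, 24 of 24 cell cycle genes and 16 of 16 housekeeping genes. Single genes passed in 4 lists. Adjusted over the list alone, 15 of 33 GR targets, 4 of 19 PR targets, 30 of 37 ER targets and 18 of 20 luminal identity genes rose and none fell. Over all 14746 genes tested 0 passed the exact stratified permutation test (smallest adjusted p = 0.0783). At an unadjusted p under 0.05, 5190 genes were higher (35.2%) and 1 was lower. At that level 23 GR targets, 13 PR targets, 30 ER targets and 18 luminal genes were higher, all within the 95% range of random lists matched on GR peaks per window (13 to 23, 7 to 14, 20 to 30 and 12 to 19). All lay above that range in lists matched on H3K27ac peaks per window (9 to 19, 4 to 11, 13 to 24 and 7 to 15). As a share of all GR peaks these lists did not differ past the threshold. Luminal genes held 0.892% ± 0.201 of GR peaks in fasted and 0.801% ± 0.385 in fed libraries (SD, n = 6 each, exact p = 0.670, adjusted p = 0.928). GR targets held 0.675% ± 0.0698 and 0.515% ± 0.229 (exact p = 0.150, adjusted p = 0.344), and ER targets 1.20% ± 0.223 and 0.860% ± 0.322 (exact p = 0.09, adjusted p = 0.275). The receptor's own gene NR3C1 had 4.0 ± 2.90 peaks in its window in fasted and 0.167 ± 0.408 in fed libraries (SD, n = 6 each, list-adjusted exact p = 0.0440). DDIT4, an inhibitor of mTORC1, had 6.17 ± 4.12 and 0.667 ± 1.03 peaks. SCNN1A, an epithelial sodium channel subunit, had 7.17 ± 5.00 and 0.5 ± 0.548, and NFKBIA, the inhibitor of NF-κB, 4.5 ± 1.87 and 0.833 ± 0.983. GADD45B (4.83 ± 3.19 and 0.833 ± 1.33), CEBPB (4.83 ± 3.25 and 1.0 ± 1.10) and KLF6 (4.33 ± 2.73 and 0.667 ± 1.03) rose as well. So did ZBTB16 (5.67 ± 3.98 and 1.17 ± 1.33) and KLF9 (2.67 ± 1.21 and 0.5 ± 0.548), transcription factors induced by glucocorticoids. A further 4 classical targets had values in the same direction that missed the list-adjusted threshold. FKBP5, a co-chaperone of steroid receptors, had 5.17 ± 3.19 and 1.5 ± 1.76 peaks (exact p = 0.03, list-adjusted 0.0550). TSC22D3, an anti-inflammatory leucine zipper protein, had 7.83 ± 5.78 and 0.333 ± 0.516 (exact p = 0.035, list-adjusted 0.0550). The clock gene PER1 had 8.17 ± 3.97 and 2.67 ± 2.88 (exact p = 0.055), and the kinase gene SGK1 1.67 ± 1.63 and 0.167 ± 0.408 (exact p = 0.05). Of PR targets, BCL2L1 (6.17 ± 2.48 and 0.833 ± 1.33), CDK2 (5.67 ± 3.20 and 0.667 ± 0.816) and TSKU (3.17 ± 1.33 and 0.667 ± 0.816) rose beside KLF9.

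ESR1, which encodes ERα, went from 1.0 ± 1.10 GR peaks in fed to 20.0 ± 9.80 in fasted libraries (SD, n = 6 each). The pioneer factor gene FOXA1 went from 2.0 ± 1.79 to 9.17 ± 3.49, and GATA3, a luminal transcription factor gene, from 0.167 ± 0.408 to 7.33 ± 6.68. Among ER targets the estrogen-induced gene GREB1 had 19.8 ± 12.3 peaks in fasted against 3.0 ± 2.76 in fed libraries, and XBP1 10.7 ± 3.72 against 2.67 ± 3.56. AGR3 had 9.33 ± 4.03 against 0.833 ± 1.60, KRT13 8.5 ± 5.21 against 1.67 ± 2.73 and KRT19 8.17 ± 4.79 against 1.5 ± 2.35. KRT8 (15.3 ± 6.62 against 3.17 ± 4.02) and KRT18 (11.7 ± 4.84 against 2.33 ± 2.88), which encode the keratins of luminal cells, rose too. GRHL2 had 12.2 ± 6.43 against 3.17 ± 3.19. GR windows of the other lists did not pass in any gene. These were 0 of 30 AP-1 and growth factor targets, 0 of 29 fasting and FOXO genes, 0 of 24 cell cycle genes and 0 of 11 basal markers. The same held for 0 of 6 fibroblast, endothelial and pericyte markers, 0 of 14 immune and adipocyte markers and 0 of 16 housekeeping genes (exact stratified permutation test, adjusted over the list alone). At an unadjusted p under 0.05, 9, 15, 10, 4, 0, 6 and 5 genes of these lists were higher in fasted libraries. The sum of calls over all lists was 67. It was 37 without Control replicate 3, 16 without TMX replicate 1 or 3, 106 without TMX plus fasting replicate 1, and 0 without both lists of fewer than 1000 peaks. Without TMX plus fasting replicate 3 it was 172, and 7882 genes passed over all genes.

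PR, which binds the same DNA element as GR, was also called at more places after fasting, but no single region passed. The geometric mean was 29548 peaks in fasted and 11436 in fed libraries, a 2.58-fold difference (log2 1.37, exact stratified permutation p = 0.025, n = 6 and 6, adjusted p = 0.188). Group means were 15402 ± 5213 peaks in Control, 12441 ± 12755 in TMX, 31458 ± 6774 in Fasting and 30799 ± 16804 in TMX plus fasting (SD, n = 3 each). Of 10590 regions tested 0 passed the Fisher exact test (smallest adjusted p = 0.110), with 1460 higher and 1 lower at an unadjusted p under 0.05. In 172 regions PR was found in all 6 fasted and no fed library. No gene passed over all 16637 genes tested (3675 higher and 0 lower unadjusted) or, adjusted over the list alone, in any of the 11 lists. TSC22D3 had 8.83 ± 4.31 PR peaks in fasted and 1.5 ± 2.35 in fed libraries (SD, n = 6 each, exact p = 0.015, list-adjusted 0.0729). ZBTB16 had 4.5 ± 3.83 and 1.0 ± 1.55 (exact p = 0.015), and PER1 10.8 ± 6.05 and 3.17 ± 3.06 (exact p = 0.035). Values for SGK1 were 3.67 ± 1.86 and 1.0 ± 1.67 (exact p = 0.05), for FKBP5 5.0 ± 3.03 and 2.0 ± 1.67 (exact p = 0.075), and for KLF9 2.5 ± 1.38 and 1.0 ± 1.10 (exact p = 0.08). The list-alone count was 48 without TMX replicate 2, 25 without TMX plus fasting replicate 3 and 6 without Fasting replicate 3. Without TMX plus fasting replicate 2 the log2 difference in peak number was 1.16 (exact p = 0.065).

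Regions that gained GR with fasting also held PR more often after fasting. A PR peak lay in 73.8% ± 13.4 of the 1895 regions in fasted and in 31.3% ± 15.8 in fed libraries (SD, n = 6 each). The difference of 42.5 percentage points passed the exact stratified permutation test (p = 0.01, adjusted p = 0.0400 over 24 tests). H3K27ac covered nearly all of them under every treatment, at 93.5% ± 1.27 in fasted (SD, n = 9) and 89.1% ± 2.96 in fed libraries (SD, n = 6). Its rise of 4.31 points passed the exact test as well (p = 0.00298, adjusted p = 0.0400). For c-JUN the shares were 69.0% ± 13.3 and 43.5% ± 21.3 (SD, n = 6 each, exact p = 0.035, adjusted p = 0.0873). For ERα they were 72.9% ± 27.8 (n = 9) and 57.6% ± 19.8 (n = 6, exact p = 0.161, adjusted p = 0.228), and neither passed. The stratified ERα difference of 18.0 points was 24.3 without TMX plus fasting replicate 5 (exact p = 0.0152), 28.5 with TMX plus fasting replicates 1 to 3 only (exact p = 0.01) and 9.98 without TMX replicate 2. In the 3020 tested GR regions that were not called, PR peaks were found in 71.7% ± 15.2 of regions in fasted and 37.7% ± 19.9 in fed libraries. The fasting difference at called regions exceeded that at the other regions by 8.46 points for PR (exact p = 0.005), 8.92 for c-JUN (exact p = 0.005) and 2.82 for H3K27ac (exact p = 0.00238). Each of these had an adjusted p of 0.0133, whereas the excess of 3.83 for ERα did not pass (exact p = 0.0976, adjusted p = 0.138). Such an excess was not particular to fasting, since the tamoxifen difference also exceeded that at the other regions, by 6.63 points for PR, 5.95 for ERα, 6.59 for c-JUN and 3.02 for H3K27ac (exact p = 0.00238 to 0.0101, all past the adjusted threshold).

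**Figure D2:**
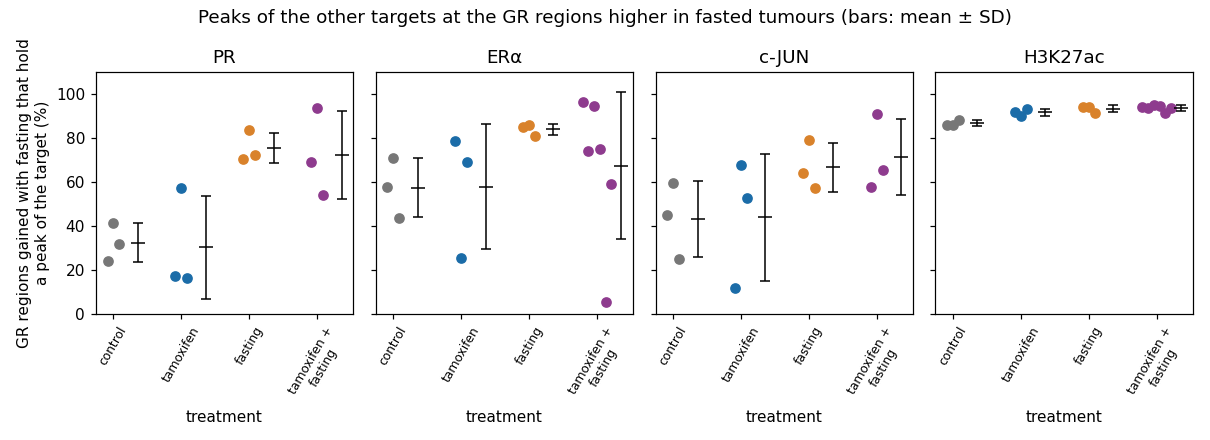
Percentage of the 1895 regions that gained GR with fasting in which each library of another target has a peak. Panels show PR, ERα, c-JUN and H3K27ac, where points are libraries and bars give the mean and SD of each treatment group. Over all fasted and all fed libraries, which the bars do not show, the PR mean is 73.8% and 31.3%. For H3K27ac it is 93.5% and 89.1%.

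ERα, the driver of MCF7 growth and the receptor that tamoxifen blocks, was found at its classical target genes in fed and fasted tumours. Neither treatment gave a difference that passed in its peak number or at single regions, nor did fasting in gene windows. The regions where H3K27ac differed with tamoxifen were an exception, as the share with an ERα peak differed by −10.5 points with tamoxifen at those that lost the mark (exact p = 0.00774, adjusted p = 0.0400). GREB1 had 39.6 ± 18.4 ERα peaks in its window in fasted (SD, n = 9) and 29.0 ± 13.8 in fed libraries (SD, n = 6, exact stratified permutation p = 0.113). TFF1, a secreted trefoil peptide gene, had 13 ± 4.80 and 9.83 ± 3.82 (exact p = 0.147), and PGR, which encodes PR, 8.33 ± 3.57 and 6.67 ± 2.42 (exact p = 0.230). XBP1 had 13.7 ± 4.92 and 12.7 ± 4.08 peaks, the cyclin gene CCND1 8.89 ± 4.08 and 9.67 ± 2.94, and MYC 6.22 ± 3.11 and 5.83 ± 3.97. Of 49315 regions tested 0 passed the Fisher exact test for fasting (smallest adjusted p = 0.617, 3258 higher and 77 lower unadjusted). For tamoxifen 0 passed the exact test as well (smallest adjusted p = 0.820, 1109 and 1237 unadjusted). Over all 18225 genes 0 passed the permutation test for fasting (1058 higher and 7 lower unadjusted), and adjusted over the list alone 0 genes passed in any list. Peak numbers were 25473 ± 10401 in Control, 30203 ± 19228 in TMX and 43906 ± 6010 in Fasting (SD, n = 3 each), and 41630 ± 25775 in TMX plus fasting (SD, n = 6). The fasting ratio was 1.31 (log2 0.39, exact p = 0.713) and the tamoxifen ratio 0.743 (log2 −0.43, exact p = 0.696). TMX plus fasting replicate 5, with 685 peaks, moved the fasting ratio, which was log2 0.90 (exact p = 0.0232) without it, when 6 list genes passed and the tamoxifen effect was log2 0.080. ERα peaks at gene ends made up 14.6% ± 3.88 of a list with tamoxifen (SD, n = 9) and 24.1% ± 8.66 without it (SD, n = 6). This difference of −9.35 points did not pass the correction (exact p = 0.0190, adjusted p = 0.0952).

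c-JUN, a subunit of the AP-1 factor that responds to growth factors and stress, showed no difference that passed in peak number, at single regions or in gene windows with fasting. Its fasting difference at the regions that gained GR passed only when set against other GR regions (8.92 points). The tamoxifen difference set against them passed as well (6.59 points), so this was not particular to fasting. Its own gene JUN had 3.83 ± 1.72 c-JUN peaks in fasted and 4.5 ± 2.74 in fed libraries (SD, n = 6 each, exact stratified permutation p = 0.735). FOSL2, another AP-1 subunit gene, had 9.67 ± 2.5 and 9.5 ± 4.23 (exact p = 1), and the stress-response gene ATF3 4.33 ± 1.03 and 4.67 ± 2.80 (exact p = 0.895). CD44, which encodes a hyaluronan receptor, had 4.5 ± 1.87 and 3.33 ± 1.97 (exact p = 0.405). Peak numbers were 33671 ± 18612 in Control, 33703 ± 21472 in TMX, 31856 ± 4444 in Fasting and 38547 ± 10080 in TMX plus fasting (SD, n = 3 each). The ratio was 1.24 for fasting (exact p = 0.530) and 1.05 for tamoxifen (exact p = 0.790). Of 11650 regions tested 0 passed the Fisher exact test for fasting (316 higher and 39 lower unadjusted) and 0 for tamoxifen (49 and 26). The permutation test of gene windows gave 0 of 18327 genes over all genes (97 higher and 127 lower unadjusted) and 0 in any list adjusted over the list alone.

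H3K27ac differed with tamoxifen at a small set of regions. Of 28616 regions tested, 84 carried the mark in 9 of 9 libraries with tamoxifen and 0 of 6 without it, and 69 in 0 of 9 and 6 of 6 (Fisher exact test, p = 0.0002, adjusted p = 0.0374). Few lay at gene ends (1.19% of the higher and 1.45% of the lower regions), and 52.4% and 47.8% lay inside gene spans. Regions that gained the mark lay inside ZNF423, a zinc finger cofactor gene (16:49540009-49543748), PLCE1, a phospholipase gene (10:94011893-94015667), and ASCC3 (6:100655409-100659693). Others were inside GALNS (16:88839506-88841984), PPFIA4 (1:203058689-203063478), GATA4, a GATA factor of heart and gut (8:11726169-11732571), and MAPK10, which encodes a JNK kinase (4:86586224-86588494). A gained region lay 44802 bp from INSC (11:15311786-15316274), another 17935 bp from GAS7 (17:10214806-10218165) and another 12656 bp from PLK2, a polo-like kinase gene (5:58439816-58442253). Regions that lost the mark lay inside CLPSL2 (6:35775948-35778130), PIP4K2A, a lipid kinase gene (10:22658866-22661273), and AGBL4 (1:48878829-48879695). LAMA3, which encodes a laminin chain (18:23720317-23724033), PDLIM2 (8:22584304-22585620) and ST3GAL3, a sialyltransferase gene (1:43833805-43837922), held further ones. A lost region lay 26583 bp from ETNPPL (4:108714117-108716473) and another 35342 bp from FBXO47 (17:39002599-39003405). A neighbouring pair lay 7696 bp from NANOGNB (12:7757245-7758351) and 7194 bp from CLEC4C (12:7756104-7757006). Leaving out any of Control replicates 1 to 3 or Fasting replicates 1 to 3 gave 0 regions (smallest adjusted p 0.0546 to 0.0811). With a library less on that side the smallest p a region can reach is larger, so this loss does not show what a single library holds. Without TMX plus fasting replicate 5 there were 375.

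Around list genes, H3K27ac peaks fell with tamoxifen at 4 hormone receptor target genes and rose at TP63, FOXO1, IGFBP1 and WNT4. Adjusted over the list alone, 1 of 22 PR targets rose and 3 fell, and 2 of 38 ER targets fell. Of fasting and FOXO genes 2 of 30 rose, of basal markers 1 of 12 rose, of housekeeping genes 1 of 16 fell, and no gene of the other lists passed. Over all genes 0 passed the exact stratified permutation test (smallest adjusted p = 0.124, 1253 higher and 1241 lower unadjusted). PGR, an estrogen-induced gene, had 11.9 ± 3.26 peaks with tamoxifen (SD, n = 9) and 18.0 ± 1.10 without (SD, n = 6, exact p = 0.00238). Its list-adjusted p was 0.0262 among PR targets and 0.0452 among ER targets. SGK3, a kinase gene induced by estrogen, had 11.2 ± 2.91 and 20.5 ± 2.43 (list-adjusted exact p = 0.0226). SGK1 had 1.89 ± 0.601 and 4.33 ± 3.56 (list-adjusted exact p = 0.0426), and ZBTB16 4.0 ± 4.18 and 10.5 ± 4.59 (list-adjusted exact p = 0.0262). Both calls hold among PR targets alone, since among GR targets their list-adjusted exact p was 0.0877 and 0.0607. The basal transcription factor gene TP63 had 32.3 ± 5.27 peaks with and 18.3 ± 5.13 without tamoxifen (list-adjusted exact p = 0.00714). FOXO1, a mediator of the response to low insulin, had 5.67 ± 1.73 and 2.0 ± 0.632, and IGFBP1, which binds insulin-like growth factors, 3.44 ± 1.13 and 0.667 ± 0.816 (list-adjusted exact p = 0.0268 for both). WNT4, a progesterone-induced ligand gene, had 3.33 ± 0.707 and 1.67 ± 1.03 (list-adjusted exact p = 0.0262). The housekeeping gene GUSB had 3.44 ± 1.13 and 8.0 ± 1.90 (list-adjusted exact p = 0.00952). The total was 10 calls, in which PGR counts in both of its lists. It was 3 without Control replicate 1, TMX replicate 1, Fasting replicate 1 or Fasting replicate 3, 2 without Fasting replicate 2, 6 without TMX plus fasting replicate 2 or 3, and 0 with only the first 3 TMX plus fasting libraries.

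Fasting gave no H3K27ac difference that passed in peak number, at single regions or in gene windows, although the mark was more frequent by 4.31 points at the regions that gained GR. The ratio of peak numbers was 1.06 (exact stratified permutation p = 0.291, n = 9 and 6). No region passed (Fisher exact test, smallest adjusted p = 0.155, 1869 higher and 1588 lower unadjusted), no gene passed over all 17795 genes tested (1121 higher and 701 lower unadjusted), and no list gene passed adjusted over the list alone. H3K27ac peaks in the GREB1 window numbered 33.3 ± 8.60 in fasted (SD, n = 9) and 41.0 ± 6.54 in fed libraries (SD, n = 6, exact p = 0.118). Those at XBP1 numbered 9.22 ± 1.64 and 7.5 ± 2.07 (exact p = 0.111), and those at MYC 4.67 ± 1.41 and 5.67 ± 1.37 (exact p = 0.183). PGR had 13.8 ± 4.35 and 15.2 ± 3.66, TFF1 12.9 ± 4.28 and 12.7 ± 2.5, and CCND1 6.0 ± 2.78 and 5.83 ± 2.56.

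Single pairs of groups set the effect of fasting beside that of its combination with tamoxifen, and with 3 against 3 libraries no exact permutation p can go below 0.1. Fasting alone gave 8.75 times the GR peaks of Control, 2.09 times the PR peaks, 1.84 times the ERα peaks and 1.11 times the H3K27ac peaks. In each case the groups did not overlap (exact p = 0.1, which chance gives in 10% of cases). For c-JUN the ratio was 1.10 (exact p = 1), and 0.713 without Control replicate 3. The GR ratio of Fasting to Control was 3.39 without Control replicate 3, 14.7 without replicate 1 and 13.4 without replicate 2. Added to tamoxifen, fasting gave 5.79 times the GR peaks of TMX (exact p = 0.2) and 3.19 times the PR peaks (exact p = 0.3). The corresponding ratios were 0.941 for ERα (exact p = 0.964), 1.41 for c-JUN (exact p = 0.8) and 1.00 for H3K27ac (exact p = 0.940). Here the GR ratio was 3.06 without TMX plus fasting replicate 2, 11.2 without its replicate 3 and 9.12 without TMX replicate 2, and the PR ratio was 5.60 without TMX replicate 2. The ERα ratio was 1.90 without TMX plus fasting replicate 5 and 0.578 without TMX replicate 2, and the c-JUN ratio was 0.823 without TMX replicate 1. At the level of regions, 6441 had GR in all 3 Fasting and no Control library and 7 the reverse. In TMX plus fasting against TMX these numbers were 523 and 5. For PR they were 3749 and 91 without tamoxifen, and 1343 and 3 with it. For ERα they were 3758 and 93, and 0 and 7, where the short list of TMX plus fasting replicate 5 also had to hold the region. For c-JUN they were 778 and 170, and 657 and 128, and for H3K27ac 1148 and 575, and 237 and 404. Chance puts 10% of the regions called in 3 of 6 libraries wholly in 1 group. With TMX plus fasting against Fasting the GR ratio was 0.458 (exact p = 0.4), or 0.242 and 0.889 without TMX plus fasting replicate 2 and 3. There 19 regions had GR in all 3 libraries of the combination and none of Fasting, while 1061 showed the reverse. TMX against Control gave ratios of 0.691 for GR (exact p = 0.8) and 0.595 for PR (exact p = 0.5). The GR ratio was 1.16, 1.06 and 0.267 without Control replicates 1, 2 and 3, and 0.439 without TMX replicate 2, and the PR ratio was 0.339 without TMX replicate 2. Over both strata, the tamoxifen ratio was 0.562 for GR (log2 −0.83, exact p = 0.385, and 0.350 without Control replicate 3) and 0.735 for PR (log2 −0.44, exact p = 0.365). No region passed the Fisher exact test with tamoxifen (0 higher and 7 lower unadjusted for GR, 10 and 106 for PR). The fasting effect on peak number was not shown to differ with tamoxifen for any target. The interaction was −0.59 on the log2 scale for GR (exact p = 0.740) and 0.61 for PR (exact p = 0.525), with p between 0.317 and 0.642 for the others.

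As a share of all peaks, no gene list passed for fasting after correction over 55 tests. GR peaks near fasting and FOXO genes made up 0.537% ± 0.0738 of a list in fasted and 0.303% ± 0.167 in fed libraries (SD, n = 6 each, exact p = 0.01, adjusted p = 0.150). Those near AP-1 and growth factor targets made up 0.442% ± 0.0284 and 0.616% ± 0.182 (exact p = 0.045, adjusted p = 0.190). PR peaks near GR targets made up 0.454% ± 0.0740 and 0.299% ± 0.122 (exact p = 0.03, adjusted p = 0.183), and those near luminal genes 0.712% ± 0.0900 and 0.898% ± 0.115 (exact p = 0.015, adjusted p = 0.150). With tamoxifen the H3K27ac share near housekeeping genes fell, from 0.219% ± 0.00590 (SD, n = 6) to 0.187% ± 0.0141 (SD, n = 9, exact p = 0.000595, adjusted p = 0.0327). The share near cell cycle genes fell as well, from 0.398% ± 0.0174 to 0.367% ± 0.0186 (exact p = 0.00179, adjusted p = 0.0491). These calls were made in 3 and 2 of the 15 runs that each left out 1 library. The 2 lists that passed became 0 without any of Control replicates 1 to 3, TMX replicates 1 to 3, Fasting replicates 2 and 3 or TMX plus fasting replicates 1 to 4, 1 without TMX plus fasting replicate 6, and 5 without TMX plus fasting replicate 5. GR peaks at gene ends made up 15.9% ± 6.57 of a list in fasted and 17.4% ± 6.14 in fed libraries (SD, n = 6 each, exact p = 0.700), and PR peaks 13.6% ± 4.63 and 14.5% ± 3.53 (exact p = 0.700). Among the strongest peaks, as many as the shortest list has, the GR difference was −9.40 points (exact p = 0.005). This decides nothing on fasting, since those 344 peaks are 100% of the shortest list and 1.04% of the longest. With a fold enrichment of at least 5 the PR difference was −5.43 points (exact p = 0.045).

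GR regions found in at least 2/3 of a group's libraries lay mostly where other factors were also found in that group, but the shares depended on this choice. Regions with GR in at least 2/3 of a group's libraries numbered 1021 in Control, 178 in TMX, 16048 in Fasting and 7068 in TMX plus fasting. H3K27ac overlapped 95% of them in Control, 89.3% in TMX, 88.6% in Fasting and 95.5% in TMX plus fasting, against 6.11% to 7.70% for random placements. ERα overlapped 82.9%, 72.5%, 69.2% and 68.5% (random 2.82% to 3.79%), and c-JUN 76.5%, 80.9%, 60.1% and 68.4% (random 2.37% to 3.17%). For PR the shares were 63.3%, 53.9%, 63.1% and 67.6% (random 0.899% to 2.01%). Seen from PR, GR overlapped 7.40% of 8992 regions in Control, 2.01% of 4835 in TMX, 41.8% of 24494 in Fasting and 23.7% of 20729 in TMX plus fasting. With regions found in any library of a group, the shares of GR regions in Control were 34.6% at PR, 42.7% at ERα, 46.3% at c-JUN and 56.5% at H3K27ac, and in TMX 41.7%, 50.4%, 54.6% and 62.3%. With regions found in all libraries, ERα overlapped 38.9% of GR regions in TMX and 12% in TMX plus fasting, where the ERα list of replicate 5 has 685 peaks. PR then overlapped 44.4% in TMX, and H3K27ac 50% in TMX and 79.0% in Control. These shares pool libraries within a group and were not tested between groups.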

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

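Tests of explanations and the splits of samples given here were chosen after the results had been seen, whereas the tests for libraries far from their group and for interactions were set beforehand.

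ERα TMX plus fasting replicate 5 stood far from the other libraries of its group of 6 in peak number and in several shares. It had 685 peaks, against 25753 to 71992 in the other 5. Of its peaks, 3.50% lay near ER targets, against 0.743% to 1.15% in the others, and 0% near GR targets, against 0.415% to 0.544%. The shares near fasting and FOXO genes (0.292%, others 0.423% to 0.447%), basal markers (0%, others 0.139% to 0.183%), fibroblast, endothelial and pericyte markers (0.146%, others 0.0750% to 0.0905%) and immune and adipocyte markers (0%, others 0.113% to 0.146%) also lay apart. In a list of 685 peaks these small shares rest on very few peaks or none. Apart from the share near ER targets, they are therefore not separate signs of a difference. H3K27ac TMX plus fasting replicate 5 stood apart in the share near basal markers, 0.168% against 0.144% to 0.152%. Groups of 6 were the only ones tested, 26 times in all, and chance gives such a library in about 1 in 20 groups. Of 65 tests of interaction, 1 had an exact permutation p under 0.05. The fasting effect on the H3K27ac share near fibroblast, endothelial and pericyte markers was −0.0161 percentage points with tamoxifen and 0.00331 without it, a difference of −0.0194 (exact p = 0.00595, not adjusted), and no explanation of it was tested.

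The gain of GR regions with fasting may be a response of the tumour to glucocorticoids, which rise in fasting animals, or may come from the material or the libraries of the fed groups. The first is a hypothesis, since the data used here hold no hormone level. Poorer tumours or chromatin in the fed groups, as far as c-JUN lists of the same replicate number track it, are argued against as the whole cause, because GR peaks over c-JUN peaks were 5.73-fold higher in fasted libraries (exact stratified permutation p = 0.015). The slope of log2 GR on log2 c-JUN peak numbers within groups was 1.36 ± 0.472 (SE, n = 12), not distinguishable from equal shortening. A correction with that slope left 5.30-fold (exact p = 0.015), and with the slope plus 2 SE 4.32-fold (exact p = 0.04). Neither the ratio nor the correction covers a fault that spares c-JUN. In TMX replicate 3, c-JUN had 49110 peaks, GR 1297 and PR 4278. Longer lists as the cause, and with them weaker GR immunoprecipitation or fewer reads in the fed libraries, cannot be told apart from more bound sites, since read numbers are unknown, PR lists were shorter in fed libraries too, and the 8 regions called from lists of 344 peaks decide nothing where 344 peaks are 100% of one list and 1.04% of another. The 344 strongest GR peaks of a library lay in H3K27ac regions in 89.6% ± 2.31 of cases in fasted and 65.7% ± 26.4 in fed libraries (SD, n = 6 each), a difference of 23.9 points (exact p = 0.08) that rests on low values in Control replicate 3, TMX replicate 1 and TMX replicate 3.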

How the results depend on the processing

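The runs without libraries of fewer than 1000 peaks, the tamoxifen test of gene windows and all alternatives for gene windows of left-out libraries or thresholds and for other targets at called regions were added after the results had been seen, whereas the other alternatives were set beforehand. The fasting difference in GR peak number kept its direction under every alternative run, between log2 1.89 and 4.08, and lay at an exact p of 0.05 or more only without both lists of fewer than 1000 peaks (1.89). The share of the regions that gained GR in which a PR peak lay was higher with fasting under every alternative. The difference stayed between 29.4 and 49.2 percentage points, with an exact p under 0.05 in all 14 alternatives. H3K27ac at these regions (3.89 to 4.75) and ERα at regions that lost H3K27ac with tamoxifen (−12.2 to −6.28) kept theirs in all 18. A longer list can raise such a share, and PR lists were longer in fasted libraries. At tested GR regions that were not called, the PR difference was 34.0 points. Counts of called regions and genes moved most. The exact p-values are coarse, so such a count depends on how many regions share the smallest p. Over all results that answer a comparison, 833 alternatives gave the same outcome, 2 a weaker and 10 a stronger one, 87 moved a value or count and 25 turned a direction. For single genes, regions and pairs these numbers were 1350, 312, 37, 88 and 78. A test counts as the same where its direction holds and its p stays on its side of 0.05. A count of 0 that stays 0 also counts as the same. Results that did not pass thus add to the same outcomes, which do not measure how firm the calls are. Motif searches, a window of 50 bp around summits included, were not run. Read depth is unknown, so it could not be varied. Unless the construction of an alternative shows it, the cause of a change was not tested.

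Replicate numbers did not pair the samples throughout, as in none of 30 pairs of groups did every same-numbered pair correlate above 0.1 (0 of 30, lowest r −0.372). In 39 of 90 comparisons over these pairs of groups, a library correlated best with its own number among 3, where chance gives 1 in 3. Each library enters several of these comparisons. Some numbers did go together, as c-JUN replicate 2 correlated at 0.119 to 0.307 in every pair of groups, against −0.156 to 0.222 for c-JUN replicates 1 and 3. A factor shared by some replicate numbers is therefore not excluded. With the replicate number as a block, 230 GR regions were called for fasting, 172 PR regions for fasting and 497 H3K27ac regions for tamoxifen. The block drops TMX plus fasting replicates 4 to 6 of ERα and H3K27ac, and there the ERα peak number was log2 1.08 higher with fasting (exact p = 0.0313) and 0.26 higher with tamoxifen. The H3K27ac tamoxifen effect was −0.018, and 0 list shares passed for tamoxifen. The block changed no other call of those it was run on, apart from ending the unadjusted one for ERα peaks at gene ends with tamoxifen. Keeping only TMX plus fasting replicates 1 to 3 without a block gave the same 1.08 (exact p = 0.005), 0.26 and −0.018, an interaction of 0.41 for ERα and −0.27 for H3K27ac (exact p = 0.04), and 508 H3K27ac regions with tamoxifen. It gave ERα ratios of log2 1.29 to TMX and 0.47 to Fasting, an H3K27ac ratio to TMX of −0.12, 33 ERα list genes with fasting, 0 H3K27ac list genes with tamoxifen and 0 list shares with tamoxifen. CCND1 then differed by 1.5 ERα and −0.667 H3K27ac peaks.

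Thresholds and equal list lengths moved these values. With a −log10 q of at least 5 the c-JUN tamoxifen effect was −0.12, the H3K27ac ratio of TMX plus fasting to TMX was −0.051, and c-JUN peaks at gene ends differed by −4.68 points with fasting (exact p = 0.005). Calls for H3K27ac list genes were then 2 with fasting and 5 with tamoxifen, and 0 list shares passed with tamoxifen. Differences in peaks were −0.333 at XBP1 and 0.333 at CCND1 for ERα, and 1.33 at ATF3 and −0.167 at FOSL2 for c-JUN. With a fold enrichment of at least 5 there were 753 GR regions, 26 GR list genes, 7 H3K27ac list genes with fasting and 1 list share with fasting. The H3K27ac fasting effect was −0.056 and its ratio of TMX plus fasting to TMX −0.15. Peaks at gene ends differed with fasting by −5.43 points for PR, −6.76 for c-JUN and 0.290 for H3K27ac. Differences in peaks were −0.417 at PGR, −0.917 at MYC and −2.08 at XBP1 for ERα, 0.667 at ATF3 and −0.667 at FOSL2 for c-JUN, and 0.167 at PGR and 1.17 at TFF1 for H3K27ac. With the strongest peaks, as many as the shortest list of the target has, there were 8 GR regions, 38 ERα regions with tamoxifen, and 2 GR, 2 PR and 2 H3K27ac list genes with fasting. H3K27ac then had 22 list genes with tamoxifen, and 1 list share passed with fasting. Gene ends differed with fasting by −9.40 points for GR (exact p = 0.005), −4.30 for c-JUN and 0.534 for H3K27ac, and with tamoxifen by −0.194 for GR. The GR values at equal length set 100% of the shortest list against 1.04% of the longest, so they decide nothing on the treatments. Differences in peaks were −0.167 at NFKBIA and −0.5 at PER1 for GR, −0.583 at GREB1, −0.0833 at TFF1 and −0.5 at XBP1 for ERα, and 1 at ATF3, −0.5 at CD44 and −0.333 at FOSL2 for c-JUN. The 5000 strongest peaks gave 110 GR regions, 44 ERα regions with tamoxifen and 0 H3K27ac regions with tamoxifen.

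Other choices of regions and windows moved counts too. Testing every region found in at least 2 libraries, which raises the number of tests, gave 0 GR and 0 H3K27ac regions, and windows of 100 bp around summits gave 0 H3K27ac regions. Windows of 10 kb gave 43 GR list genes, and differences of −0.25 ERα peaks at both TFF1 and XBP1. Windows of 100 kb gave 122 GR, 21 PR and 2 H3K27ac list genes with fasting, 1 list share with fasting, and differences of 0.833 ERα peaks at CCND1 and 0.167 c-JUN peaks at ATF3. Without both GR lists of fewer than 1000 peaks there were 0 GR regions and 0 GR list genes, and the interaction was 0.27.

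Leaving out each library in turn gave these ranges, from lowest to highest. For GR the interaction ranged from −1.52 to 0.77, the ratio of TMX to Control from −1.90 to 0.22, regions from 0 to 6485, genes over all genes from 0 to 7882 and list genes from 16 to 172. GR at gene ends ranged from −2.93 to 1.02 points with fasting and −1.31 to 3.28 with tamoxifen, and at the regions higher in H3K27ac with tamoxifen from −4.07 to 8.73. For PR the fasting effect ranged from 1.11 to 1.77, the ratio of TMX plus fasting to Fasting from −0.56 to 0.072, list genes from 0 to 48, and gene ends from −2.39 to 0.637 with fasting and −0.566 to 2.46 with tamoxifen. For ERα the fasting effect ranged from 0.043 to 0.90, the tamoxifen effect from −0.66 to 0.080 and the interaction from −1.67 to 0.051. ERα ratios ranged from −0.41 to 0.76 for TMX to Control, −0.79 to 0.93 for TMX plus fasting to TMX and −1.24 to 0.11 for TMX plus fasting to Fasting. ERα list genes ranged from 0 to 6, and ERα peaks differed by −0.75 to 1.75 at MYC, −0.417 to 2.47 at XBP1 and −1.42 to 0.833 at CCND1. For c-JUN the fasting effect ranged from −0.074 to 0.53, the tamoxifen effect from −0.24 to 0.46 and the interaction from −0.41 to 0.98. Its ratios ranged from −0.49 to 0.45 for Fasting to Control, −0.73 to 0.67 for TMX to Control and −0.28 to 0.93 for TMX plus fasting to TMX. c-JUN gene ends ranged from −3.83 to −1.38, and its peaks differed by −1.25 to 0.25 at ATF3 and −1.58 to 1.17 at FOSL2. For H3K27ac the ratio of TMX plus fasting ranged from −0.069 to 0.048 to TMX and −0.073 to 0.0087 to Fasting. Its regions with tamoxifen ranged from 0 to 375, list genes from 0 to 2 with fasting and 2 to 12 with tamoxifen, and list shares with tamoxifen from 0 to 5. H3K27ac peaks differed by −1.17 to 0.583 at PGR and −1.33 to 0.167 at TFF1.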

Other observations

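All tests in this part were chosen after the results had been seen, apart from the region and gene window tests that the splits refer to.

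How far glucocorticoid and estrogen targets stood out in GR peaks after fasting depended on the genes they were set against. Of the GR targets, 23 of 33 had more GR peaks in fasted libraries at an unadjusted p under 0.05, while 10000 random lists of genes matched on mean peaks per window gave a mean of 18.2 (95% between 13 and 23), which puts the list at percentile 97.6. ER targets reached 30 of 37 (random mean 24.9, 95% between 20 and 30, percentile 98.1), luminal identity genes 18 of 20 (random mean 15.9, percentile 87.9) and PR targets 13 of 19 (random mean 10.8). AP-1 and growth factor targets lay low, at 9 of 30 (random mean 12.3, percentile 6.93), and housekeeping genes had 5 of 16 (random mean 6.14, percentile 26.4). Cell cycle genes had 10 of 24 (random mean 9.70), fasting and FOXO genes 15 of 29 (random mean 12.9) and basal markers 4 of 11 (random mean 4.71). For PR peaks, GR targets had 13 of 34 (random mean 8.47, percentile 96.0) and ER targets 19 of 38 (random mean 12.9, percentile 98.1). All of these counts lay within the 95% range of their random lists. This matching uses fasted libraries too, so it can remove part of a change. With genes matched on H3K27ac peaks per window, GR targets (random mean 13.7), PR targets (7.46), ER targets (18.9) and luminal genes (10.7) lay above the range for GR, and so did ER targets for PR (range 7 to 18), but this matching leaves the number of GR sites per window free, so neither decides. With genes matched on gene span the same GR lists lay above the range, with random means of 11.2, 6.71, 12.9 and 7.13, and so did GR targets (range 3 to 12) and ER targets (4 to 14) for PR. Percentiles describe these libraries and were not adjusted for the number of lists.

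ERα itself differed at the regions where H3K27ac was lost with tamoxifen. An ERα peak lay in 9.66% ± 5.89 of the 69 regions in libraries with tamoxifen (SD, n = 9) and in 20.3% ± 7.10 without it (SD, n = 6), a stratified difference of −10.5 points (exact stratified permutation p = 0.00774, adjusted p = 0.0400 over 24 tests). At these regions the differences of −14.3 points for PR, −7.25 for GR and −8.45 for c-JUN did not pass the adjusted threshold. Set against tested regions that were not called, the differences were −11.4 points for ERα, −12.6 for PR, −4.42 for GR and −8.99 for c-JUN. All of the latter passed it. At the 84 regions that gained H3K27ac the corresponding values were 13.1 for ERα, 16.5 for PR and 17.3 for c-JUN, which passed. That of 6.80 for GR did not (exact p = 0.270). The tamoxifen differences at these 84 regions alone passed for no target, at 14.0 points for ERα, 14.9 for PR, 17.9 for c-JUN and 3.97 for GR. With fasting, peaks at these 84 regions were more frequent by 17.9 points for GR, 17.3 for PR and 18.3 for c-JUN (exact p = 0.01, adjusted p = 0.0400 each), and set against other tested regions this passed for c-JUN alone (12.2 points, exact p = 0.03, adjusted p = 0.0480). A difference in peak number between the groups is argued against as the cause of these H3K27ac regions by the 45.1% of them that were lower with tamoxifen, and errors of single H3K27ac libraries are argued against by the ERα lists, made with another antibody (exact p = 0.00119 at the lower regions). A change in enhancer use under tamoxifen may underlie the set, as a hypothesis found and tested on the same data, but a difference between the tumours sampled, or a fault of chromatin that ERα and H3K27ac libraries share, stays open.

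Libraries of the same replicate number deviated alike across targets. The values compared were log2 peaks per gene window, from which the group mean of each gene was taken. Each library's own mean was then taken out too. This removes a shift that is equal in all windows. A longer list adds more in windows with many peaks, so list length was not fully removed. Among GR, PR and c-JUN, libraries of the same number in a group correlated across targets in these deviations (mean r 0.138, permutation p = 1e-05, the smallest these permutations can give). In 28 of 36 comparisons a library correlated best with its own number, where chance gives 12. Over all 5 targets the mean r was 0.0440 (permutation p = 0.00351, 65 of 120 where chance gives 40). List lengths that go together across targets may give such correlations and were not tested apart. Between PR and ERα in TMX, where replicate 2 had 27139 and 9312 peaks, the mean r of same-numbered libraries was −0.286. Another candidate explanation is that same-numbered libraries were made from the same tumour or chromatin, so that the GR and PR results of a group may not be independent of each other. The labels do not say so, and the effect of fasting on PR at GR regions was not tested apart from it.

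Other splits of the same samples show which counts chance can reach. Among 100 splits of the 12 GR libraries into 6 and 6, 2 called as many regions as the real 1898 of the fasting contrast. The other of these called 2231, after TMX plus fasting replicate 3 and TMX replicate 2 had changed places. For H3K27ac regions with tamoxifen, 1 of 100 splits, the real one, gave 153 regions and the highest other gave 0. For GR gene windows adjusted over each list alone, 1 of 100 splits within the tamoxifen strata gave as many as the real 67, the highest other giving 17, and for H3K27ac with tamoxifen 1 of 100 splits within the fasting strata gave as many as the real 10, the highest other giving 7. A share under 0.05 of the drawn splits reached these counts and that of the GR regions. Only 100 of 462 possible GR region splits were drawn, without tamoxifen strata, and 1 other split exceeded the real count. The splits were chosen after the results were seen, so chance is not excluded. Where the real count was 0, all 100 splits were as large by definition. The highest other split then gave 0 for PR and c-JUN regions in both contrasts, ERα and H3K27ac regions with fasting, and gene windows over all genes of GR, PR, c-JUN and H3K27ac, and it gave 0 for PR, 4 for c-JUN and 8 for H3K27ac gene windows with fasting adjusted over each list alone. For GR with tamoxifen the highest other split gave 2231 regions and is the split that nearly follows fasting. For ERα it gave 4866 regions in the tamoxifen contrast, 5282 genes over all genes and 120 adjusted over each list alone. The 4866 regions came from a single split, which set Control replicates 1 to 3, Fasting replicate 3, TMX replicate 2 and TMX plus fasting replicate 5 apart from the rest. It shares 7 of 9 libraries with the real tamoxifen split and sets lists of 685 to 36995 peaks against lists of 25753 to 71992, so it points to a structure of the ERα samples that was not tested apart from tamoxifen or list length. At an unadjusted p under 0.05 the real fasting split of PR had 1461 regions, and 2 of 100 splits had as many, the highest other reaching 1897.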
